A study of Mus musculus with 6 samples.

How the data were processed

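Total RNA from mouse CD4+CD25+ natural regulatory T cells and CD4+CD25- conventional T cells was compared on 6 two-colour miRNA arrays. Per the labels, the CD4+CD25+ sample carried Cy5 on 3 arrays (1, 3 and 5 by the number in their titles) and Cy3 on 3 (2, 4 and 6), and the series design describes 3 biological replicates with a dye swap of each. The labels do not say which arrays belong to one replicate or whether replicates came from separate animals. The p-values measure the spread between these replicates, which limma pooled largely over the probes, so they do not follow from each probe's SD alone. How the cells were sorted, labelled and scanned, and the software and any genome build, are not given in the sources used here.

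The deposited table holds the authors' log ratio of both channels for 178 probes per array, taken here as log2; the log base, any background correction, normalization or centring, and the direction of the ratio are not stated by the labels or the file header. The values as deposited had array medians of -0.118, -1.785, -0.3045, -1.265, 0.081 and -1.7875 for arrays 1 to 6, so the arrays were not median-centred. Scanner intensities were not used here, so signal over background is unknown, and no probe could be marked as dim. Depth has no meaning for these values, and the number of arrays limits their precision.

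A rule set before the data were examined turned the sign of the arrays with CD4+CD25+ cells in Cy3 if arrays of opposite dye correlated below 0. The correlations over miRNA probes ranged from -0.369 to 0.251 with a median of -0.058, so the arrays were turned, by a narrow margin. Arrays of one orientation correlated at 0.521 to 0.622 (CD4+CD25+ in Cy5) and 0.901 to 0.918 (CD4+CD25+ in Cy3). The 24 probes called under both centrings correlated between turned arrays of opposite dye at 0.552 to 0.906, but were chosen on the turned values.

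Probes were named by the number in their ID. The platform table gave 1 symbol for 61 of the 171 miRNA probes, several for 1 and none for 109. Of the 61 symbols, 59 matched the ID's number, where a number without a letter was matched to the a form (miR-20 to the 20a gene), and 2 differed (probes 1org-34a and 1org-34c). Probes numbered 7 with a letter are let-7 members. The probe for miR-181 was taken as miR-181a in the lists. The miR-7 probe was left out of the lists, although the neural list as fixed names miR-7. The 2 prefixes of the probe IDs are not explained in the sources used here. No coordinates are given, since no genome build is named. The RefSeq gene table of GRCm38.p6 served only to find miRNA genes that neighbour each other.

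The main test was limma (version 3.58.1, R 4.3.3), lmFit with an intercept and eBayes on 3 replicate values per probe, each the mean of a pair of arrays of opposite dye, so that a dye effect equal on both arrays cancels. All 6 ways of pairing the arrays were fitted, and a probe passed when its Benjamini-Hochberg adjusted p was under 0.05 in each; the largest p and SD are reported. An exact sign-flip test of 3 replicates cannot give a two-sided p below 0.25, so none was used. The dye effect was tested with limma on 6 arrays with a column for the dye. Of 23 miRNA lists, fixed before the data were examined, the 18 with at least 3 measured probes were tested with camera (preset correlation 0.01, largest p of the 6 pairings, Benjamini-Hochberg over the lists), with an estimated correlation and fry as alternatives. Named probes were the 12 largest passing differences in each direction, a fixed set (miR-155, miR-146, miR-21, miR-223, both arms of miR-142, miR-150, miR-181a, miR-10a, miR-31 and miR-125a), and from each tested list its 2 largest differences and up to 4 members past the test (with fewer than 12 passing, all of them and up to 8 in all by size; this was not needed). Values outside this rule (miR-7, miR-122a, miR-144, miR-153, miR-17-5p and the small nuclear RNA and tRNA probes) were chosen after their values were seen.

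The steps were tested on simulated data with 171 probes in 20 simulations of this comparison. The test recovered 72.0% of simulated changes of 1 on the log2 scale and 97.2% of changes of 2, with 2.3% false calls among the calls and 0 of the wrong sign. The simulation held no offset of dim probes and no shift shared by the probes of an array. It took the turning as known, drew changes of both signs alike and tested no centring. Its rate of false calls need not hold for these arrays. Alternatives fixed before the data were examined were median centring, scale normalization, other pairings and models of the 6 arrays, single dye orientations, leaving out noisy probes, a robust fit, leaving out each pair of opposite arrays, and the opposite sign. Scale normalization multiplied each array by its own factor. The arrays with CD4+CD25+ cells in Cy5 then carried more weight, so a dye effect need not cancel under it. Centring on the off-tissue probes or on U6 and the tRNAs, the requirement of a call under both centrings, leaving the arrays unturned, and an estimated correlation combined with median centring or scale normalization were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.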

Results

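Natural regulatory T cells, the CD4+CD25+ cells that restrain other T cells, were compared with conventional CD4+CD25- T cells of the mouse for their microRNAs (miRNAs), small RNAs that lower the output of the messenger RNAs they pair with. Total RNA of the 2 cell populations was hybridised together on 6 two-colour arrays, which stood for 3 biological replicates, each with a dye swap. The CD4+CD25+ sample carried Cy5 on 3 arrays and Cy3 on the other 3. Each array gave a log ratio for 178 probes with no missing value, of which 171 were miRNA probes and 7 were probes for small nuclear RNAs or tRNAs. The number of arrays limits the precision. Every ratio below is the log2 ratio of CD4+CD25+ over CD4+CD25- cells, reading the deposited ratio as Cy5 over Cy3; this direction is likely from the order of the channels but the value table does not state it, and with the opposite reading every sign turns. The log base is not stated either and was taken as log2. Nor does the table state whether the authors had already turned the dye-swapped arrays; if so, 21 of the 24 probes named below as called under both centrings would have the opposite sign, and 3 of the 24 would pass as deposited (miR-126*, miR-20 and miR-10a), while miR-223 would stand at -0.066 ± 0.950 (SD, n = 3; limma adjusted p = 0.901). Errors are SDs with n = 3 replicates, each the mean of a pair of arrays of opposite dye. Because the labels do not say which arrays formed a pair, the largest SD and the largest adjusted p over the 6 possible pairings are given. The limma p-values rest on a variance pooled largely over all probes, so they do not follow from the SDs printed beside them.

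The question was which miRNAs differ between regulatory and conventional CD4+ T cells. With the arrays turned, the largest ratio was that of miR-223, best known from myeloid cells, at 4.12 ± 0.855 (SD, n = 3), or 17.3-fold, and it was higher on 6 of 6 arrays (limma adjusted p = 0.000103). miR-214 followed at 2.91 ± 1.60 (adjusted p = 0.00569). Its largest standard error in limma was 0.491, less than that SD alone would give, so the p-value is lenient for so uneven a probe. miR-23a stood at 1.82 ± 0.730 (adjusted p = 0.00464), miR-125a at 1.74 ± 0.292 (adjusted p = 0.00132) and the miR-146 probe, for a miRNA induced by NF-kB signalling, at 1.72 ± 0.517 (adjusted p = 0.00411). At the other end, miR-30b was lower in CD4+CD25+ cells with a log2 ratio of -1.33 ± 0.544 (adjusted p = 0.00411), and miR-150, an abundant miRNA of resting lymphocytes, with -1.03 ± 0.255 (adjusted p = 0.00569), each on 6 of 6 arrays. After scale normalization, which gave more weight to the arrays with CD4+CD25+ cells in Cy5, miR-223, miR-23a, miR-125a and miR-146 kept their calls. The calls of miR-214 (3.39 ± 2.36, adjusted p = 0.0578), miR-30b (-1.35 ± 0.795, adjusted p = 0.0726) and miR-150 (-1.08 ± 0.483, adjusted p = 0.0711) were lost as the spread grew and the difference did not shrink.

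As deposited, 130 of the 171 miRNA probes passed the test, 115 of them higher and 15 lower in CD4+CD25+ cells, so 88.5% of the calls were higher. The excess of higher calls came mainly from one dye orientation. The arrays with CD4+CD25+ cells in Cy3 alone gave 122 higher and 25 lower, with turned array medians of 1.83, 1.29 and 1.82. Those with CD4+CD25+ cells in Cy5 alone gave 12 higher and 7 lower, with medians of -0.085, -0.31 and 0.097. Scale normalization left 9 higher and 4 lower. The count also moved with the zero point. The median probe had a log2 ratio of 0.82, and 27 probes for miRNAs of other tissues (epithelium, muscle, liver, nervous system and embryonic stem cells) had a median of 0.87 and ranged from 0.55 to 1.25. Of these, 25 were called higher. After each array was centred on its median, 9 probes were higher and 39 lower, so 18.8% of the calls were higher, and 0 of the 27 off-tissue probes passed in limma (2 at an unadjusted p under 0.05). The miR-7 probe, left out of the neural list and so not among the 27, lay below their range. It had 0.24 as deposited, not called, and was called lower after median centring (-0.53, limma adjusted p = 0.0386). Centring on U6 and the tRNAs instead, a choice made after the data were seen, gave 127 calls, of which 2 were lower. For this reason the account below leads with the probes called in one direction both as deposited and after median centring, a criterion also added after the data were seen. Median centring lowered the mean ratio of every probe, so this criterion screened the higher calls only. It kept all 15 lower calls as deposited and is no test of them.

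By that criterion 9 probes were higher in CD4+CD25+ cells: miR-223, miR-214, miR-23a, miR-125a, miR-146, miR-297, miR-207, miR-10a and miR-126*. Relative to the array median, miR-223 stood at 3.34 ± 0.654 (SD, n = 3), miR-214 at 2.14 ± 1.35, miR-23a at 1.05 ± 0.547, miR-125a at 0.97 ± 0.314 and miR-146 at 0.95 ± 0.360. miR-10a, encoded in a Hox gene cluster, had 1.47 ± 0.331 as deposited and 0.69 ± 0.195 relative to the median. For 5 of the 9 the ratio depended on the dye. The means on the arrays with CD4+CD25+ cells in Cy5 and in Cy3 were 0.13 and 2.81 for miR-10a, 0.50 and 2.23 for miR-126*, 0.76 and 2.48 for miR-297, 0.75 and 2.42 for miR-207 and, the other way round, 2.46 and 1.17 for miR-23a (limma adjusted p of the dye column 0.0219 or less). The miR-297 and miR-207 probes were also uneven, at 1.62 ± 0.927 and 1.59 ± 1.10. miR-207 passed after centring only narrowly (adjusted p = 0.0498). miR-10a and miR-126* were not called when the arrays were centred on the off-tissue probes, which kept 7 of the 9. After scale normalization 4 of the 9 kept both calls, and miR-214, miR-297, miR-207, miR-10a and miR-126* did not.

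**Figure D1:**
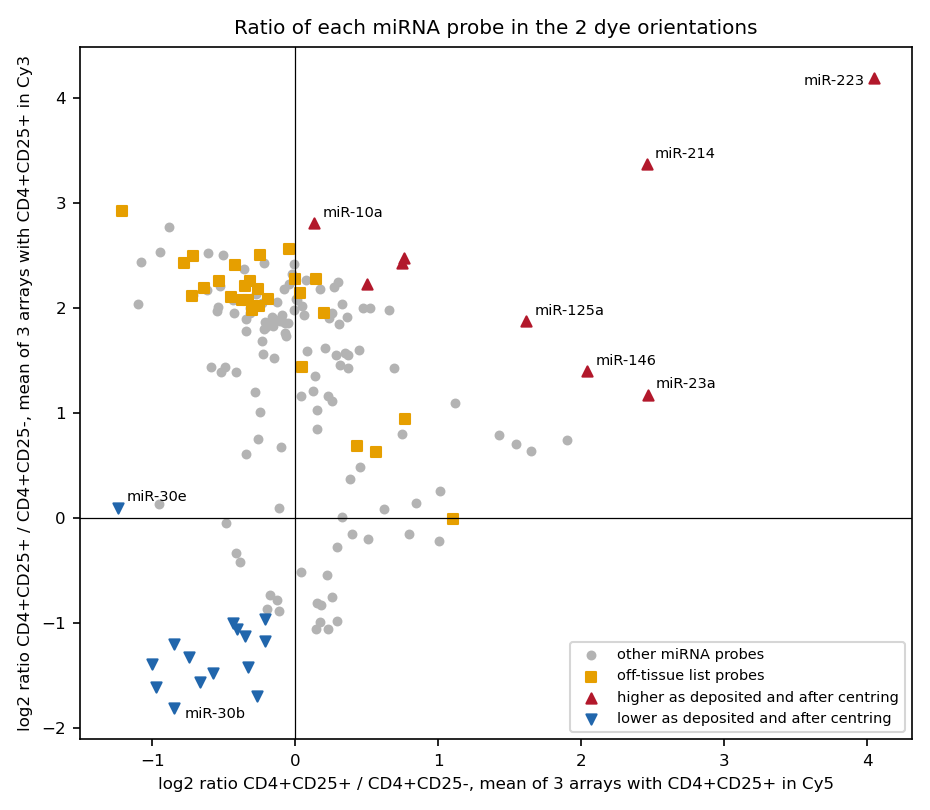
Each point is 1 of the 171 miRNA probes, with the mean log2 ratio of CD4+CD25+ over CD4+CD25- cells on the 3 arrays with CD4+CD25+ cells in Cy5 (x axis) and on the 3 arrays with CD4+CD25+ cells in Cy3 (y axis); triangles mark probes called both as deposited and after median centring, and squares the 27 off-tissue probes. miR-223 lies near 4 on both axes (4.05 and 4.18), while most off-tissue probes lie near 0 on the x axis and near 2 on the y axis.

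By the same criterion 15 probes were lower in CD4+CD25+ cells, the same 15 as without centring, and 11 of them were below 0 on 6 of 6 arrays. They were miR-30b, miR-30c and miR-30e, miR-142-as and miR-142*, miR-26a and miR-26b, miR-29a and miR-29b, let-7b and let-7c, miR-19a and miR-20, miR-150 and the miR-181 probe. Relative to the array median, miR-30b stood at -2.10 ± 0.517 (SD, n = 3), miR-142*, a further probe named for miR-142, a miRNA made by blood cells, at -2.06 ± 0.252, miR-142-as at -1.97 ± 0.262 and miR-150 at -1.81 ± 0.299. Which strand the miR-142* probe measures is not stated, so it and miR-142-as may not be separate findings. As deposited, miR-142-as had -1.20 ± 0.440 and miR-26b -1.11 ± 0.779. The strand labelled miR-142-s did not pass as deposited, with -0.27 ± 0.538 (adjusted p = 0.347). After median centring it was called lower (-1.04, limma adjusted p = 0.00158). For 4 of the 15, miR-20, miR-30e, let-7b and miR-181, the ratio depended on the dye (limma adjusted p of 0.00514 to 0.0496). miR-30e was lower in 1 dye orientation, with a mean of -1.24 with CD4+CD25+ cells in Cy5 and 0.10 with them in Cy3. Of the 15 probes, miR-30b and miR-142* were the 2 still called lower after centring on U6 and the tRNAs. After scale normalization 4 of the 15 kept both calls: miR-142-as, miR-142*, miR-19a and miR-30e. miR-30e then moved from -0.57 to -1.13, towards its mean with CD4+CD25+ cells in Cy5. The probes that lost a call all stayed below 0, from -0.47 (miR-29a) to -1.35 (miR-30b).

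**Figure D2:**
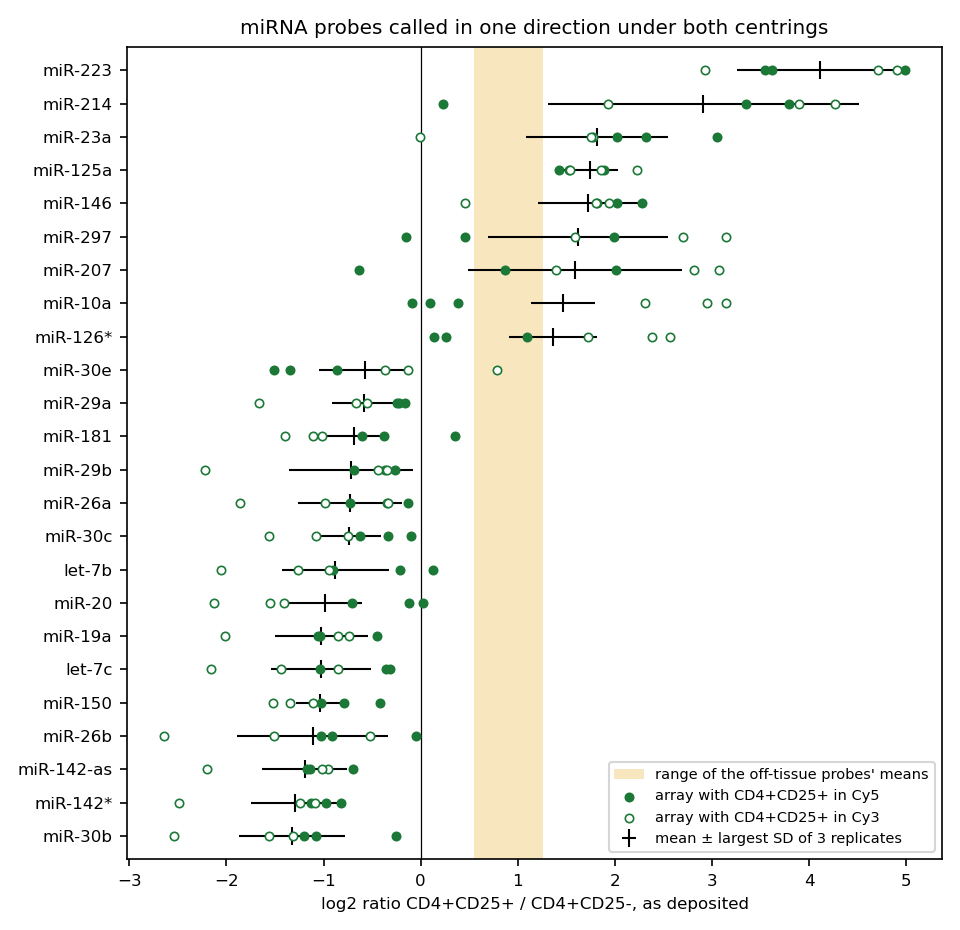
Log2 ratios of CD4+CD25+ over CD4+CD25- cells, as deposited, for the 24 probes called in one direction both as deposited and after median centring. Filled circles are the arrays with CD4+CD25+ cells in Cy5 and open circles those with CD4+CD25+ cells in Cy3, the tick and bar are the mean and the largest SD of 3 replicates, and the band is the range of the off-tissue probes (0.55 to 1.25); the means of all 9 higher probes lie to the right of the band.

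Among miRNAs often studied in T cells, miR-155, induced on T cell activation and a target of the regulatory T cell factor Foxp3, had a ratio of 1.23 ± 0.453 (SD, n = 3; limma adjusted p = 0.00569), miR-21 had 1.13 ± 0.530 (adjusted p = 0.00709) and miR-31 had 1.07 ± 0.302 (adjusted p = 0.00569). These 3 values passed as deposited but lay within the range of the off-tissue probes, and after median centring they did not pass (0.46 with adjusted p = 0.0883, 0.35 with adjusted p = 0.184 and 0.30 with adjusted p = 0.268). miR-23b at 1.32 ± 0.670 and miR-221 at 1.27 ± 0.573 lay just above that range and also did not pass after centring (adjusted p = 0.0675 and 0.0628). miR-24 had 1.11 ± 0.383 and was above 0 on 6 of 6 arrays, with adjusted p = 0.216 after centring. After scale normalization miR-21, miR-23b and miR-24 passed as higher under both centrings (adjusted p = 0.0137, 0.0156 and 0.0172 without centring).

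Fixed lists of related miRNAs were then compared with the other probes. The list of miRNAs high in resting T cells and lower after activation stood lowest: 9 of its 13 measured members were lower, 1 was higher (miR-101, at 0.84 ± 0.311) and 3 did not pass, with 9 lower also when adjusted over the list alone. Its median was -0.69, or -1.46 relative to the array median and -0.28 with centring on U6 and the tRNAs (camera adjusted p = 3.79e-08, and adjusted p = 0.698 with an estimated correlation). The miR-30 family, which is part of it, had 3 of 5 members lower (median -0.57, or -0.15 with centring on U6 and the tRNAs, camera adjusted p = 0.00218; 2 lower adjusted over the list alone), and the miR-29 family, also part of it, 2 of 3 (median -0.59, or -0.17 with that centring, camera adjusted p = 0.0134; 2 adjusted over the list alone). Both calls were lost with an estimated correlation (adjusted p = 0.698 for each). Of the 9 let-7 family probes, let-7b and let-7c were lower, miR-98 was higher at 0.96 ± 0.536 and 6 did not pass, around a median of -0.35, which turned to 0.071 with centring on U6 and the tRNAs (camera adjusted p = 0.00218, and adjusted p = 0.698 with an estimated correlation). Of the 11 probes of the miR-17/miR-92 clusters, which drive lymphocyte growth, miR-19a at -1.02 ± 0.477 and miR-20 at -0.98 ± 0.383 were lower, miR-17-3p at 1.32 ± 0.952 and miR-18 at 0.79 ± 0.510 were higher and 7 did not pass (median -0.40, or 0.012 with centring on U6 and the tRNAs; camera adjusted p = 0.00139, and adjusted p = 0.698 with an estimated correlation). With scale normalization the let-7 and miR-17/miR-92 lists did not pass (adjusted p = 0.072 and 0.0517). Adjusted over the list alone, the let-7 and miR-17/miR-92 counts were also 2 lower each, with 1 and 2 higher. After median centring 7 let-7 probes and 9 miR-17/miR-92 probes were lower and none higher. The higher calls of miR-17-3p (0.55, adjusted p = 0.157), miR-18 (0.016, adjusted p = 0.966), miR-98 (0.19, adjusted p = 0.556) and miR-101 (0.066, adjusted p = 0.857) ended with that centring.

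The list of miRNAs tied to regulatory T cells in the literature stood higher than the other probes, with 13 of 13 members higher as deposited and also when adjusted over the list alone (median 1.32, camera adjusted p = 0.00854, and adjusted p = 0.698 with an estimated correlation). The list median was 0.55 relative to the array median, 0.37 with off-tissue centring and 1.74 with centring on U6 and the tRNAs. Under both centrings 6 were higher: miR-223, miR-214, miR-23a, miR-125a, miR-146 and miR-10a. This list may include the study behind these arrays, so it is not independent evidence of the direction.

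**Figure D3:**
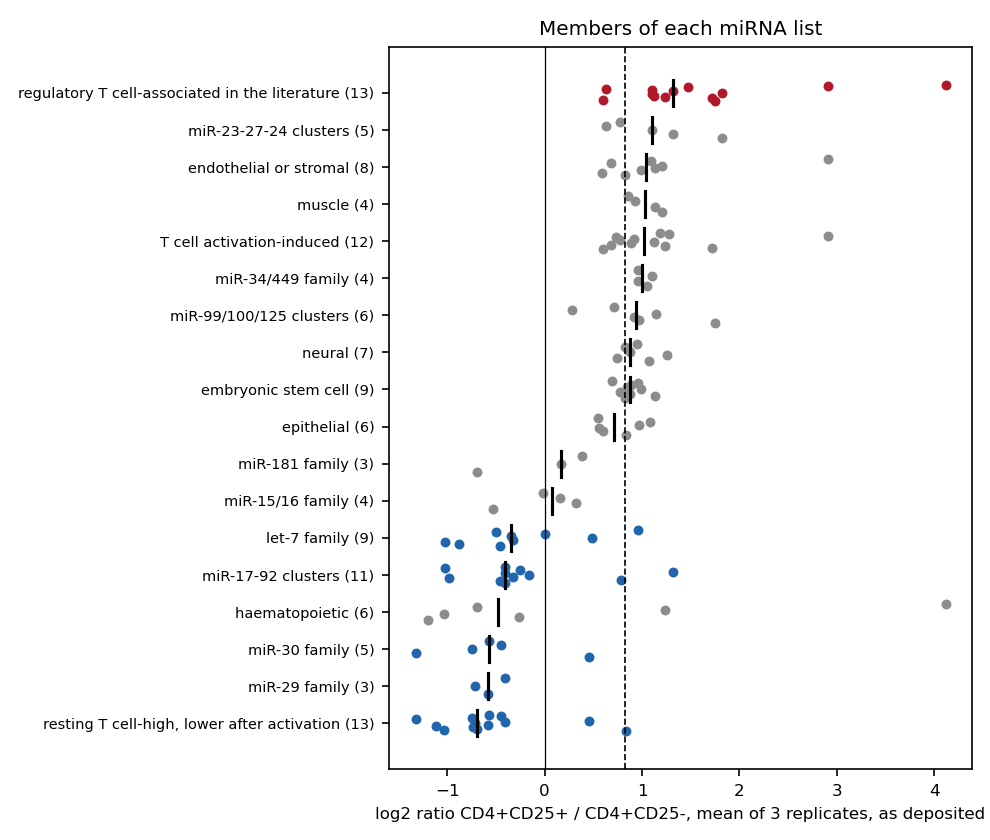
Log2 ratio of CD4+CD25+ over CD4+CD25- cells, as deposited, for each measured member (points) of the 18 lists tested, with the number of members in brackets; thick bars are list medians, the dashed line is the median of all miRNA probes (0.82), and red or blue lists passed camera with the preset correlation above or below the other probes. The list high in resting T cells has the lowest median (-0.69) and the regulatory T cell list the highest (1.32).

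The remaining 12 tested lists did not pass. The list induced by T cell activation had 12 of 12 members higher as deposited and 2, miR-214 and miR-146, under both centrings (median 1.02, camera adjusted p = 0.0747, and 0.031 after median centring; with an estimated correlation adjusted p = 0.698 and 0.638). The haematopoietic list split, with miR-223 and miR-155 higher, miR-142-as, miR-150 and miR-181 lower and 1 not passing, so that its median (-0.48) and its mean (0.36) differed in sign (camera adjusted p = 0.287). Of the miR-23-27-24 clusters 5 of 5 probes were higher (median 1.11) and of the miR-99/miR-100/miR-125 clusters 5 of 6 (median 0.94, or -0.011 with off-tissue centring), with 1 probe each, miR-23a and miR-125a, higher under both centrings and camera adjusted p = 0.287 for both lists. With scale normalization the miR-23-27-24 clusters passed as higher (shift against the other probes 1.19, camera adjusted p = 0.00338), as did the activation-induced list (adjusted p = 0.029). With an estimated correlation as well, tried after the data were seen, neither passed (adjusted p = 0.683 and 0.788). The miR-34/miR-449 family had 4 of 4 higher (median 1.00, camera adjusted p = 0.287) and 0 under both centrings. The miR-15/16 family had 0 of 4 called (median 0.071, mean -0.017, camera adjusted p = 0.183), although 3 of them were lower after median centring (median -0.70). The miR-181 family had 1 of 3 lower (median 0.17, or -0.60 after median centring, mean -0.047, camera adjusted p = 0.23).

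Lists for other cell types sat near the array median. Their medians were above 0 as deposited and lay between -0.058 (epithelial) and 0.26 (endothelial or stromal) relative to the array median. As deposited, 4 of 6 epithelial probes (median 0.72), 4 of 4 muscle probes (1.03), 7 of 7 neural probes (0.88), 9 of 9 embryonic stem cell probes (0.87) and 8 of 8 endothelial or stromal probes (1.04) were higher, and none was lower. The neural count leaves out the miR-7 probe, which was not called (0.24). Under both centrings the count was 0 in each of these lists except the endothelial or stromal one, where miR-214 was higher. Their camera adjusted p values were 0.593, 0.287, 0.287, 0.287 and 0.183. Lists with fewer than 3 measured probes were not tested: the liver probe miR-122a had 0.86, the erythroid probe miR-144 0.69, the myeloid list held miR-223 alone, the miR-10 family had 2 of 2 higher (median 1.10) and the miR-26 family 2 of 2 lower (median -0.92).

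Adjusted over the list alone, the remaining lists gave 12 higher for the activation-induced list, 5 each for the miR-23-27-24 and miR-99/miR-100/miR-125 clusters, 4 for miR-34/miR-449, 0 for miR-15/16, 1 lower for miR-181, 2 higher and 3 lower for the haematopoietic list, and 6 epithelial, 4 muscle, 7 neural, 9 embryonic stem cell and 8 endothelial or stromal probes higher.

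The other 7 small RNA probes had lower ratios than the median miRNA probe. U6, a spliceosomal RNA often used as a reference, had a mean log2 ratio of -0.69 ± 0.452 (SD, n = 3), below 0 on 5 of 6 arrays, and the tRNA probes had -0.92 ± 0.742 (alanine), -0.49 ± 0.430 (histidine), -0.16 ± 0.440 (methionine) and -0.063 ± 0.303 (proline). The other 2 small nuclear RNA probes stood at 0.54 ± 0.348 and 0.32 ± 0.245. These values were not tested.

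The ratio also depended on the dye. In the fit over 6 arrays, 120 of the 171 miRNA probes had a dye effect (limma), 108 brighter in Cy3 and 12 brighter in Cy5, and 78 did after median centring. As limits on the counts above, leaving out a pair of opposite arrays left between 0 calls (without arrays 3 and 2; 98 at an unadjusted p under 0.05) and 127, with 2 without arrays 5 and 6, 59 without 1 and 2, 64 without 1 and 6 and 80 without 5 and 2, and between 0 and 12 higher and 0 and 14 lower under both centrings. All 24 probes called under both centrings kept their sign in 9 of 9 such fits, but their calls were less stable. miR-223 kept both calls in 8 of the 9 fits, miR-30b, miR-150, miR-142-as, miR-142*, miR-19a, miR-20 and let-7c in 7, miR-125a, miR-146, miR-23a, miR-26b and let-7b in 6, miR-26a and miR-30c in 5, miR-214 and miR-10a in 4, miR-297 and miR-29b in 3, miR-207 and miR-181 in 2, miR-126* and miR-30e in 1 and miR-29a in 0.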

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

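The dye test and median centring were planned; the use of centring to test a scaling factor and the other tests in this part were chosen after the data were seen. The turned ratio of 120 of the 171 miRNA probes differed between both dye orientations by the limma test of the dye column, with a median Cy5 over Cy3 effect of -0.77 on the log2 scale, and 30 probes had one sign on the 3 arrays of one orientation and the opposite sign on the 3 of the other. The strongest was the miR-153 probe, a neural miRNA, at -2.07, chosen after its value was seen.

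Most probes were called higher in CD4+CD25+ cells as deposited, 25 of the 27 off-tissue probes and 90 of the 144 others. The share differed between lists of miRNAs studied in T cells. It was 1 of 13 in the list high in resting T cells and 13 of 13 in the regulatory T cell list. A single scaling factor for all probes stays open as a cause of the excess of higher calls: median centring left 9 of the 115 higher calls, though 28.1% of all probes still passed, 39 of them lower. An offset of dim probes between Cy5 and Cy3 that was equal on all arrays is excluded as the sole cause. It would cancel over both orientations, while the array medians of the 27 off-tissue probes averaged 0.95 ± 0.402 (largest SD, n = 3). A dye offset that differed in size between the orientations would not cancel and stays open. Those medians averaged -0.26 with CD4+CD25+ cells in Cy5 and 2.17 with them in Cy3. An offset of dim probes that follows the CD4+CD25+ sample may account for most of the 115 higher calls: the off-tissue probes, expected to be dim in T cells, had a median of 0.87, close to the 0.82 of all probes. On average they were above 0 only with CD4+CD25+ cells in Cy3, so such an offset would need a dye effect beside it. A general rise of miRNAs in CD4+CD25+ cells was not tested and stays open, since no scanner intensity was used. The split of the arrays by dye gave 130 calls and the highest of the other 9 splits 0, but 10 splits are too few for a share under 0.05 (the real split is 1 of 10).

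The probes lower in CD4+CD25+ cells have a related open question. U6 and the tRNAs were also lower, with a median of -0.49, so less labelled small RNA of every kind in the CD4+CD25+ channel could lower these probes too. Not every such value was lower: the other 2 small nuclear RNA probes stood at 0.54 ± 0.348 and 0.32 ± 0.245. On array 3 the median of U6 and the tRNAs was 0.49. After centring on U6 and the tRNAs, 2 of the 15 lower calls stayed (miR-30b at -0.91 and miR-142* at -0.88). The median of the 15 probes moved from -0.98 (median SD 0.473) to -0.57 (median SD 0.616), and 15 of 15 stayed below 0. The other 13 had a smaller difference than as deposited, with a larger SD for 11 of them and a smaller one for 2. The smaller difference need not be the only reason for the lost calls. With this centring miR-142-as did not pass at -0.78 (limma adjusted p = 0.0717), while miR-181 passed as deposited at -0.69 (limma adjusted p = 0.0159). This explanation and a lower level of these miRNAs in CD4+CD25+ cells cannot be told apart here, because 5 reference probes of uneven ratio set the zero point.

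miR-223 was higher by 3.34 relative to the array median and also passed with each other centring. Myeloid cells among the CD4+CD25+ cells could bring it; how the cells were sorted is not given in the sources used here. The myeloid list fixed beforehand held 1 measured probe, miR-223 itself, so myeloid cells and expression by the T cells cannot be told apart. For the 24 probes called under both centrings, the split by dye gave 24 and the highest other split 0, again 1 of 10 splits and too few for a share under 0.05.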

How the results depend on the processing

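Centring on the off-tissue probes or on U6 and the tRNAs and leaving the arrays unturned were chosen after seeing the data; the cause of a change was not tested unless stated. The requirement of both centrings was itself added then. Against 130 calls as deposited (115 higher, 15 lower; 9 and 15 under both centrings), median centring gave 48 (9 and 39), scale normalization 13 (9 and 4; 9 and 4 under both, sharing 4 and 4 with those as deposited), off-tissue centring 47 (7 and 40) and U6 and tRNA centring 127 (2 of them lower). The 6 arrays as independent without a dye term gave 5 (5 and 0, with 10 lower at an unadjusted p under 0.05; 1 and 0 under both), as the dye effect then counts as noise; with a dye term they gave 141. Arrays with CD4+CD25+ cells in Cy5 alone gave 19 (12 and 7; 12 and 6 under both), those with them in Cy3 alone 147 (122 and 25; 39 and 25 under both). Turning the sign gave 15 higher and 115 lower (15 and 9 under both), by construction. Unturned arrays gave 91 calls (3 and 88; 3 and 18 under both), and 21 of the 24 probes then had the opposite sign; which reading is right rests on the turning rule and was not settled otherwise. Pairing by consecutive title numbers gave 130, the same numbers as a random replicate block 132 (117 higher, 15 lower; 13 and 15 under both), leaving out the noisiest 10% of the probes 113 and a robust fit 131. Residuals of consecutive arrays correlated at 0.197 (1 and 2), -0.047 (3 and 4) and 0.114 (5 and 6), so the numbers do not establish pairs.

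Leaving out a pair of opposite arrays gave 0 to 127 calls (0 to 115 higher, 0 to 14 lower; 0 to 12 and 0 to 14 under both) and 6 to 7 lists. There were 0 without arrays 3 and 2 (98 at an unadjusted p under 0.05; 47 passed after median centring), 2 without 5 and 6, 59 without 1 and 2, 64 without 1 and 6 and 80 without 5 and 2, while the other 4 pairs left 115 to 127; the cause was not tested. The 6 lists became 0 with an estimated correlation (0 at an unadjusted p under 0.05), 0 with fry (5) and 0 with fry for either direction (7), but fry tests a list against no change, not against the other probes, and shows no loss of a shift. The count was 6 or 7 under the other alternatives with the preset correlation. With scale normalization the let-7 and miR-17/miR-92 lists no longer passed (adjusted p = 0.072 and 0.0517), and the miR-23-27-24 and activation-induced lists passed (adjusted p = 0.00338 and 0.029). Among the higher probes under both centrings, miR-214, miR-297, miR-207, miR-10a and miR-126* left and miR-21, miR-22, miR-23b, miR-24 and miR-99b entered (adjusted p 0.0109 to 0.0211; miR-22 was named after its value was seen). The list induced by activation had adjusted p values between 0.0254 and 0.788 over its alternatives, the highest with scale normalization and an estimated correlation together, added after seeing the data; that pairing and median centring with an estimated correlation each left 0 lists. The dye effect fell from 120 to 78 probes after median centring.

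Changes of sign were followed for the 65 named probes only, and other probes that changed sign are not given here. Among the named probes, single values past the test as deposited or in the alternative that changed sign were 1org-200a under median centring (-0.18), 1org-294 under scale normalization (-0.0068) and 1org-30e with CD4+CD25+ cells in Cy3 alone (0.099). With CD4+CD25+ cells in Cy5 alone they were 1org-101 (-0.32), 1org-125b (-0.13), 1org-129 (-0.046), 1org-137 (-0.26), 1org-141 (-0.31), 1org-18 (-0.22), 1org-199-s (-0.0093), 1org-1b (-0.25), 1org-1d (-0.35), 1org-203 (-0.32), 1org-291-as (-0.0027), 1org-292-s (-0.42), 1org-294 (-0.72), 1org-295 (-0.26), 1org-34a (-0.080), 1org-34b (-0.61), 2org-199b (-0.044) and 2org-219 (-0.19). Under off-tissue centring they were 1org-101 (-0.11), 1org-137 (-0.071), 1org-141 (-0.12), 1org-18 (-0.16), 1org-1d (-0.026), 1org-200a (-0.36), 1org-206 (-0.098), 1org-27b (-0.18), 1org-294 (-0.062), 1org-99a (-0.036), 2org-181c (-0.57) and 2org-219 (-0.0078). Values past the test in neither that changed sign were 1org-15b (-0.45 under median centring, -0.15 with CD4+CD25+ cells in Cy3 alone, -0.63 under off-tissue centring), 2org-181c (-0.39 under median centring, -0.25 with CD4+CD25+ cells in Cy5 alone) and 1org-142-s (0.15 under U6 and tRNA centring). A filter on missing values and averaging probes of one name change nothing, as there were 0 missing values and 0 duplicate names, and were not run; the turned sign was run for counts only, and the unturned arrays for counts and the 24 probes.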

Other observations

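The follow-up of neighbouring miRNAs without the off-tissue probes was chosen after its first result was seen. Among the other probes of the miR-17/miR-92 clusters, the 2 strands of one precursor lay apart, with miR-17-3p called higher at 1.32 and miR-17-5p at -0.25, not called. After median centring miR-17-3p was not called (0.55, limma adjusted p = 0.157) and miR-17-5p was called lower (-1.02, adjusted p = 0.000827). Probes from one genomic cluster also differed, such as let-7c at -1.03 beside miR-99a at 0.92. The value of miR-99a lay within the range of the off-tissue probes. After median centring miR-99a was not called (0.14, limma adjusted p = 0.686) and let-7c was called lower (-1.80, limma adjusted p = 6.58e-05). These pairs were picked after their values were seen, and their differences were not tested.

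A hypothesis was that miRNAs encoded within 10 kb of each other differ alike between the cell types. For 67 such pairs of measured miRNAs, same-numbered pairs left out, the mean absolute difference between the log2 ratios was 0.558, against 0.782 in 10000 shuffles (one-sided permutation p = 0.0276). Without the off-tissue probes, which sit close together, 52 pairs remained with 0.689 against 0.858 (one-sided permutation p = 0.0931), and 12 of them had opposite signs. Adjusted over both tests, the p values were 0.0552 and 0.0931, so the data are at most weakly consistent with the hypothesis. Pairs share probes and are not independent, and related sequences in a cluster can cross-hybridise.

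Array 3 stood apart for the reference RNAs. The median turned ratio of U6 and the tRNAs was 0.49 on array 3, and -0.55, -0.70, -0.63, -0.44 and -0.67 on arrays 1, 2, 4, 5 and 6. Without array 3 and one of arrays 2, 4 and 6, the probes called under both centrings numbered 0, 24 and 25.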
